A study of Homo sapiens with 12 samples.

How the data were processed

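RNA was measured by sequencing of polyadenylated transcripts, per the labels, in HCT116 cells, a human colorectal carcinoma line. The cells were wild type (WT) or carried a knockout of KDM3A (KO). Each genotype was sampled in 3 culture states. Mock cells grew in normal medium, starved cells in medium without serum, and refed cells had fetal bovine serum added after 24 h without it. The time between serum addition and harvest is not given. The labels list 12 samples, 2 in each of the 6 groups. The deposited files are 6 tables of 26372 gene symbols, each with 1 column named for its group and not for a replicate. How the 2 samples of a group relate to its column is not stated, so each group was treated as a single value and no spread between replicates could be estimated. The values are FPKM computed by the authors, fragments scaled by transcript length and by mapped fragments. Per the labels, reads were trimmed with cutadapt and aligned to human genome build hg19 with TopHat2, with no versions given. The program that computed FPKM and its gene annotation are not named in the sources used. Genes were identified by symbol, and no coordinates are given. For a test of neighbouring genes, the order of genes along chromosomes was taken by symbol from a RefSeq gene table of a later genome build, GRCh38. Of the symbols, 25271 matched a current symbol or alias.

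Read counts were not used here, so the depth of each library is unknown and no counting interval can be given. Values were used as deposited, and log2 ratios were taken of (FPKM + 1). The 13456 features at 1 FPKM or more in at least 1 group were compared. Of these 406 were short RNA features (small nucleolar RNA, microRNA and similar), whose FPKM is unstable because of their length. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.

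KO was compared with WT in each state, starved with mock and refed with starved in each genotype, which made 7 comparisons of 1 value with 1 value. These have no test: genes that differed at least 2-fold were counted, with no p. The 2 responses, to starvation and to serum, were subtracted between genotypes in the same way. For 3 comparisons averaged over the other factor, limma fitted culture state and genotype as additive terms to the 6 values, with a trend of the variance on expression. The fit leaves 2 residual degrees of freedom, which are the interaction of genotype and state. Its adjusted p (Benjamini-Hochberg over the 13456 features, threshold 0.05) therefore measures how even a difference was across states or genotypes, and not how it compares with replicate error. "Rose" and "fell" are used of genes that passed this threshold, and "higher" and "lower" of values that had no test.

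The comparisons, settings, alternatives, the rule for named genes and 26 gene lists were chosen before the data were examined. The lists were YAP/TEAD targets, Hippo pathway components, immediate early genes, SRF/MRTF cytoskeletal genes, ERK feedback genes, cholesterol synthesis and uptake, fatty acid synthesis, DNA replication, mitosis, hypoxia targets, FOXO targets, p53 targets, Wnt targets, the ATF4 response, H3K9 methylation enzymes, interferon-stimulated genes, NF-kB and chemokine genes, epithelial markers, mesenchymal markers, intestinal differentiation, germline genes, fibroblast, leukocyte, and hepatocyte and neuron markers, stress chaperones and mitochondrial transcripts. A list of 16 endothelial genes was added after WT mock values of other genes had been seen and before its own were. For each list the median log2 ratio was compared with 10000 random lists matched on expression in 10 bins. The 21 lists with at least 4 measured genes were also tested in the averaged comparisons with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 and again with an estimated one, adjusted over lists. Because values on the deposited scale shifted between groups, list medians are given relative to the median of all genes unless said otherwise, and counts of members are on the deposited scale.

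Named genes were KDM3A and, per comparison, the 6 largest differences in each direction at 5 FPKM or more in the higher group and past the threshold. For KO against WT over the states these also had to differ 2-fold in the same direction in all 3 states. CTGF, CYR61, ANKRD1 and AMOTL2 were followed in every group, and up to 4 members with the largest differences were taken from each list. Features without a gene symbol, short RNA features and read-through genes were not named. On simulated values, limma recovered 100% of 100 genes shifted by 1 and 100% of 100 shifted by 2 on the log2 scale, and 6.98% of its 215 calls were unshifted genes. The simulation had equal shifts in all 3 states, independent noise, no effect of state and no shift of all genes between groups. It left out short RNA features and the genes 4-fold higher in WT mock than elsewhere. It therefore does not show what share of the real calls is right. Of 80 unshifted random lists, 6.25% fell outside the central 95% of matched lists, as did 100% of 20 lists shifted by 0.5. These lists were drawn at random from independent simulated values, so the rate does not cover lists whose genes move together. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-ratio and upper-quartile rescaling, a 1.5-fold threshold, a fit without the variance trend, and leaving out each value or state. Removing short RNA features, genes listed at 0 in any group, or the genes 4-fold higher in WT mock than elsewhere were alternatives chosen after seeing the data.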

Results

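FPKM values of 26372 genes were available for 6 groups of HCT116 cells, WT or KO for KDM3A, in mock, starved and refed culture, with 1 value per group. KDM3A encodes a demethylase of histone H3 lysine residues. Between 12170 (WT refed) and 12648 (WT mock) genes were at 1 FPKM or more. The read depth is unknown. The summed FPKM was 481036 in WT refed and 1.15e+06 in WT mock, where the small nucleolar RNA SNORD81 alone was listed at 593431. Without short RNA features the sums ranged from 444361 (WT refed) to 593683 (KO refed). WT starved and WT refed stood apart in low values, with 4300 and 4301 genes listed at 0 against 6401 in WT mock and 7075 to 7312 in the KO groups. Across genes, correlations between groups were 0.924 to 0.978, though genes are not independent replicates.

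KDM3A itself was at 41.3 FPKM in WT mock, 17.8 in WT starved and 19.8 in WT refed. In KO the levels were 3.15, 3.01 and 3.59 FPKM, or 7.64%, 17.0% and 18.2% of WT in the same state. Averaged over states KDM3A fell (log2 -2.58, SE 0.26, adjusted p = 0.00730). CTGF, a secreted matricellular protein and target of the co-activator YAP, was at 62.3 FPKM in WT mock, 1.24 in WT starved and 64.0 in WT refed, and at 1.34, 1.20 and 5.09 in the same KO states. CYR61, a related YAP target, was at 27.8, 7.66 and 444 FPKM in WT and 14.7, 16.6 and 309 in KO. ANKRD1 was at 34.2 FPKM in WT mock and at 0.169 or less in the other 5 groups. It is among 87 genes at least 4-fold higher in WT mock than in every other group, where endothelial genes described below were also high. The WT mock value of CTGF comes from the same group. AMOTL2, which binds YAP, was higher in KO in every state, at 10.9, 11 and 24.4 FPKM against 4.0, 2.94 and 14.6 in WT mock, starved and refed.

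**Figure D1:**
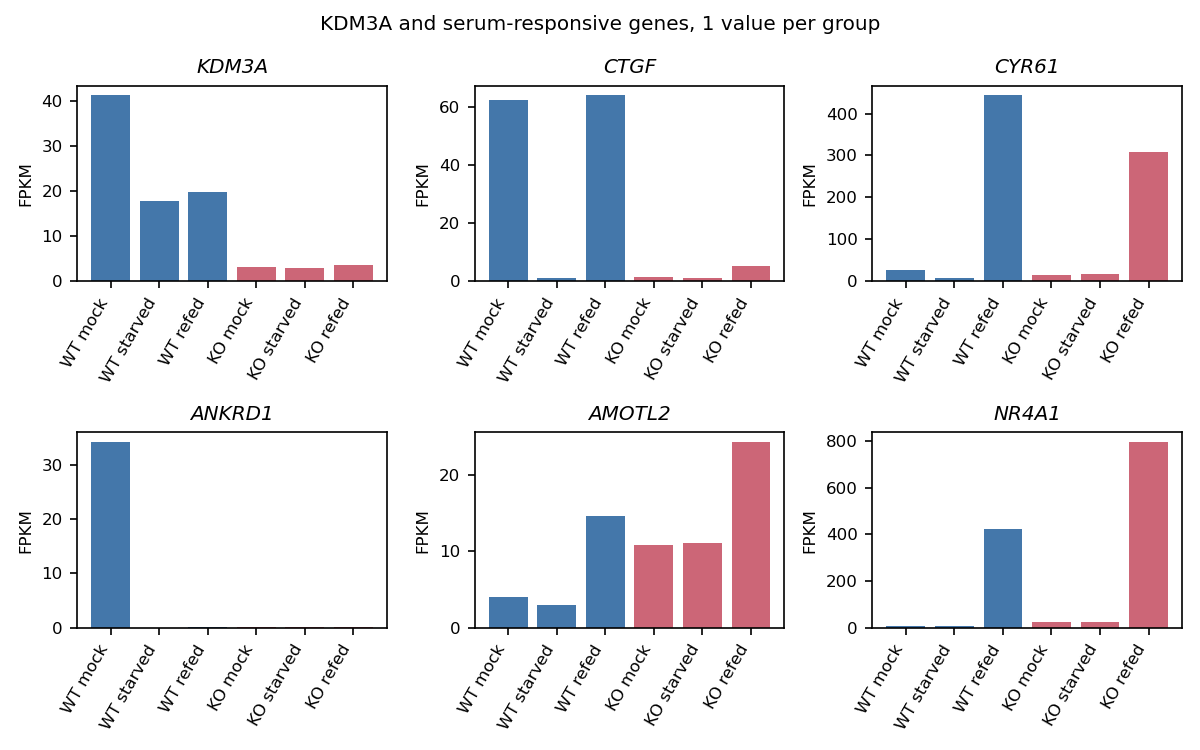
FPKM of KDM3A, CTGF, CYR61, ANKRD1, AMOTL2 and NR4A1 in the 6 groups, 1 bar per group, WT in blue and KO in red, with a linear axis from 0 in each panel. KDM3A is lower in KO in each state, and CTGF in refed cells is at 64.0 FPKM in WT and 5.09 in KO.

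KO was compared with WT to ask which transcripts differ when KDM3A is lost. LY6D, a surface protein of squamous epithelium, was at 137, 134 and 194 FPKM in KO mock, starved and refed and at most 2.35 in any WT group. MYL2 and TNNC1, subunits of the contractile apparatus of striated muscle, were also higher in KO. MYL2 was at 10.1 to 22.3 FPKM there and at most 0.0832 in WT, and TNNC1 at 30.0 to 44.6 against 2.21 to 2.37. In the other direction, SPARC, a matrix protein, was at 60.8 to 83.3 FPKM in WT and at most 0.0193 in KO. The nuclear receptor NR2F1 was at 94.6 to 115 FPKM in WT and 1.66 to 4.17 in KO.

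Averaged over states, the genes with the largest rises included LY6D (log2 5.76, SE 0.15, adjusted p = 0.00151), MYL2 (4.08), TNNC1 (3.54), the gastrin gene GAST (3.11) and the membrane protein EMP1 (2.91). SPARC fell the most (log2 -6.09, SE 0.11, adjusted p = 0.00138), then NR2F1 (-4.88), the vitamin D 24-hydroxylase CYP24A1 (-3.92), STMN2 (-3.69), ARHGAP29 (-3.62) and the interferon-induced BST2 (-3.40). STMN2, a neuronal microtubule regulator, was at 9.29 to 17.2 FPKM in WT and was listed at 0 in KO starved and refed. All of these differed at least 2-fold in the same direction in all 3 states. CDKN1C, an inhibitor of cyclin-dependent kinases, was among the largest differences in refed cells alone, at 61.9 FPKM in KO and 5.16 in WT. KLK5 and KLK10, kallikrein proteases with close paralogs, were at 14.4 and 26.3 FPKM in KO mock and 0.630 and 2.71 in WT mock. RNA18S5, a ribosomal RNA, was listed at 0 in all KO groups, and EEF1A1 was listed at 3742 FPKM in WT refed and at 0 in the other 5 groups; EEF1A1 has many processed pseudogenes and its value is uncertain.

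In mock culture the largest differences were of another kind. WT mock cells had the intermediate filament gene VIM at 153 FPKM, the matrix protein THBS1 at 175, the collagenase MMP1 at 84.3, von Willebrand factor (VWF) at 75.9 and the proteoglycan BGN at 64.0. KO mock cells had 0.0640, 1.30, 0.143, 0.113 and 0.0124 FPKM of the same genes. These genes moved with endothelial markers: 14 of 16 endothelial genes were at 1 FPKM or more in WT mock and at least 2-fold above every other group, such as ENG at 33.2, CDH5 at 25.8, PECAM1 at 15.5 and TIE1 at 12.8 FPKM. The endothelial median was -2.44 between KO and WT mock on the deposited scale. In all, 87 genes apart from short RNA were at least 4-fold higher in WT mock than in every other group; the same count was 0, 3, 0, 0 and 2 for WT starved, WT refed, KO mock, KO starved and KO refed.

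**Figure D2:**
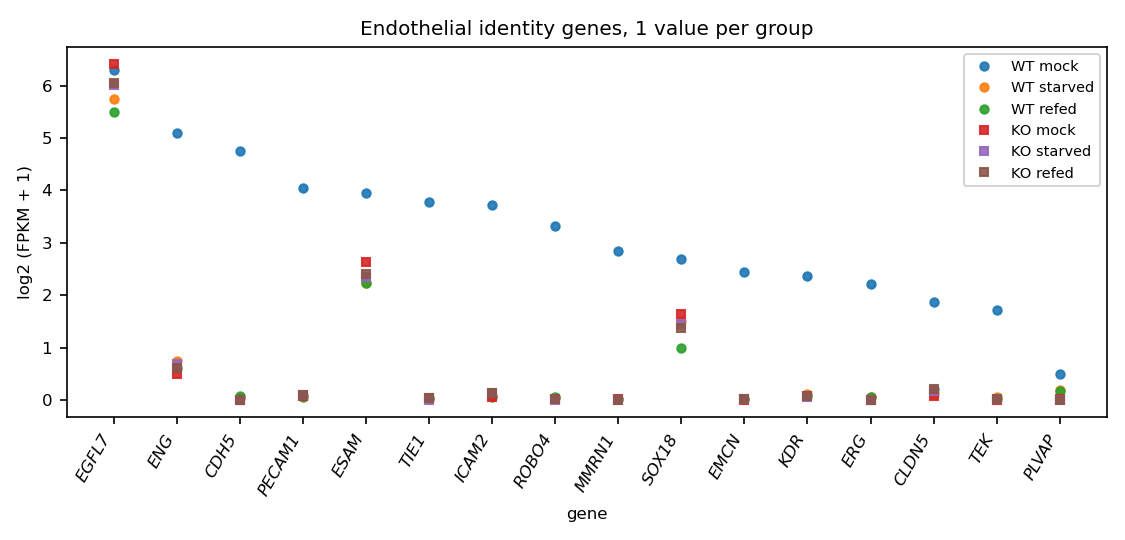
Log2 of (FPKM + 1) of the 16 endothelial genes in the 6 groups, with WT as circles and KO as squares. In WT mock 15 of the 16 are at 1 FPKM or more, and EGFL7 is high in every group.

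At 2-fold or more, 305 genes were higher and 433 lower in KO than in WT in mock culture, 348 and 196 in starved cells, and 459 and 203 in refed cells. The median log2 ratio of all genes was 0.07, 0.19 and 0.22 in these states. After median-ratio rescaling the starved split was 241 higher and 271 lower, and the refed split 308 and 283; without the 87 genes and the short RNA features 4-fold higher in WT mock the mock split was 305 and 338, and among genes at 5 FPKM or more it was 242 and 216, which turns the direction of the majority. In all 3 states 171 genes were higher and 81 lower, where independent lists of the same sizes would share 0.269 and 0.0951. Averaged over states, 3867 genes rose and 616 fell, with 277 and 121 of them at 2-fold or more and a median of 0.16 for all genes. After median-ratio rescaling 1616 rose and 1504 fell, after upper-quartile rescaling 1459 and 1719, and without the filter on low values 741 and 241. Leaving out a value leaves 1 residual degree of freedom: the fit then called 5 genes without WT starved, 25 without WT refed, 6 without KO starved and 32 without KO refed, but 5713 without WT mock and 5719 without KO mock.

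Over all 13456 features 3867 rose and 616 fell on the deposited scale, and the list counts below include that shift. Among the lists, genes of cholesterol synthesis and uptake were higher in KO as a group. Of 24 measured, 22 rose and 0 fell averaged over states (22 and 0 adjusted over the list alone), with a median of 0.74 relative to all genes. INSIG1, which restrains sterol synthesis, was at 12.2, 25.9 and 54.7 FPKM in WT and 47.4, 64.8 and 124 in KO, and IDI1, ACAT2 and the synthase HMGCS1 had log2 differences of 1.24, 1.17 and 1.16. Camera gave adjusted p = 7.60e-08 with the preset correlation and adjusted p = 0.386 with an estimated correlation. Fatty acid synthesis genes rose in 9 of 10 (10 adjusted over the list alone), led by FASN (log2 1.03) and ACSL3 (0.83). The adjusted p was 0.00449, and adjusted p = 0.386 with an estimated correlation. Epithelial markers rose in 11 of 12 (11 adjusted over the list alone), with a median of 0.60. The claudin CLDN3 had log2 0.90; KRT8, KRT18 and KRT19 had 1.25, 1.22 and 1.13, which are uncertain because keratins have close paralogs and pseudogenes. The adjusted p was 0.000685, and adjusted p = 0.386 with an estimated correlation.

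NF-kB and chemokine genes were lower in KO. Of 10, 0 rose and 5 fell (0 and 5 adjusted over the list alone), with a median of -0.60. The neutrophil chemoattractants CXCL8 and CXCL1 fell by 2.73 and 1.36 on the log2 scale, and CXCL1 was at 3.76, 6.96 and 8.33 FPKM in WT against 1.56, 1.49 and 2.26 in KO. Camera gave adjusted p = 2.48e-07, and adjusted p = 0.386 with an estimated correlation. Mesenchymal markers, the same way by camera (adjusted p = 0.00708, and adjusted p = 0.881 with an estimated correlation), had 2 genes that rose and 2 that fell of 12 (2 and 2 adjusted over the list alone). SPARC and ZEB2 fell and the collagens COL6A1 and COL6A2 rose; ZEB2, COL6A1 and COL6A2 were chosen after their values were seen. VIM, FN1 and MMP2 were at 153, 139.6 and 43.1 FPKM in WT mock, beside the endothelial genes above, and at 1.78 or less elsewhere.

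Wnt targets had a median of 0.74 relative to all genes, and 7 of 13 rose and 1 fell (7 and 1 adjusted over the list alone). The list had adjusted p = 0.334 by camera and adjusted p = 0.881 with an estimated correlation. The secreted Wnt inhibitors NOTUM and DKK1 were at 9.99 and 205 FPKM in WT mock and 36.9 and 656 in KO mock, and ZNRF3, a Wnt receptor ligase, had log2 1.59. Interferon-stimulated genes moved both ways: 10 of 16 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.253, and adjusted p = 0.881 with an estimated correlation). IFI27 and IFI6 rose (log2 1.88 and 1.62), and IFITM1 fell (-2.21). Immediate early genes had 2 that rose and 2 that fell of 18 (2 and 2 adjusted over the list alone), with adjusted p = 0.0221 and adjusted p = 0.873 with an estimated correlation; the nuclear receptor NR4A1 rose (log2 1.4) and the transcription factor EGR1 fell (-1.21). DNA replication genes rose in 12 of 23 (14 adjusted over the list alone; adjusted p = 0.0368, and adjusted p = 0.873 with an estimated correlation), with CDC6 at log2 0.64; in refed cells the median of 0.25 on the deposited scale became -0.02 after median-ratio and -0.05 after upper-quartile rescaling.

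YAP/TEAD targets split: 3 of 19 rose and 2 fell (3 and 2 adjusted over the list alone), AMOTL2 among the first (log2 1.19) and the ectonucleotidase NT5E among the second (-1.12). CTGF averaged log2 -2.73 with adjusted p = 0.0826, and the list had adjusted p = 0.0712, and adjusted p = 0.881 with an estimated correlation. Both averages include the WT mock value, in which endothelial genes were also high. Of the list, 3 genes are among the 87 that were 4-fold higher there than in every other group. CTGF was at 62.3 FPKM in WT mock and 1.34 in KO mock, at 1.24 and 1.20 in starved cells, and at 64.0 and 5.09 in refed cells. Of the Hippo pathway components, 7 rose and 1 fell of 20 (8 and 1 adjusted over the list alone). Over all features 3867 of 13456 rose, and the Hippo, hypoxia and p53 counts that rose are near that share or below it. WWTR1, which encodes the YAP relative TAZ, fell (log2 -1.20, adjusted p = 0.00432), and VGLL4 and WWC1 rose (0.77 and 0.74). Hypoxia targets had 7 that rose and 1 that fell of 20 (9 and 1 adjusted over the list alone): the glucose transporter SLC2A1 rose (log2 2.18) and carbonic anhydrase CA9 fell (-1.60). For p53 targets these counts were 4 and 2 of 18 (4 and 2 adjusted over the list alone), with GDF15 and BAX fallen (log2 -1.61 and -1.16). ERK feedback genes gave 2 and 2 of 12 (2 and 2 adjusted over the list alone), with EPHA2 and DUSP4 risen and SPRY4 fallen.

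In the other lists with at least 4 measured genes, counts of genes that rose and fell were 5 and 1 of 14 FOXO targets (5 and 1 adjusted over the list alone), 4 and 0 of 22 mitosis genes (0 and 0), 2 and 0 of 16 ATF4 response genes (2 and 0), 3 and 0 of 16 other H3K9 methylation enzymes (2 and 0), 0 and 0 of 13 SRF/MRTF genes (0 and 0), 0 and 1 of 10 stress chaperones (0 and 1), and 1 and 0 of 4 intestinal differentiation genes (1 and 0). Among these lists only FOXO targets had a larger share that rose than all features, of which 3867 of 13456 rose. The averaged medians of the Hippo, SRF/MRTF, ERK, FOXO, p53, ATF4, H3K9 and chaperone lists lay between 0.03 and 0.17 on the deposited scale and turned negative after median-ratio rescaling. Of the lists too small to test, germline genes had MAGEA3 measured (26.6 FPKM in WT mock, 23.3 in KO mock), fibroblast markers COL1A1 (23.6 and 18.7), leukocyte markers CD68 (12.2 and 32.9), and hepatocyte and neuron markers SERPINA1 (1.49 and 1.85) and MAP2 (4.0 and 4.92). CD68, a lysosomal protein, rose (log2 1.66, adjusted p = 0.00373). None of the 10 mitochondrial transcripts was among the measured genes.

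**Figure D3:**
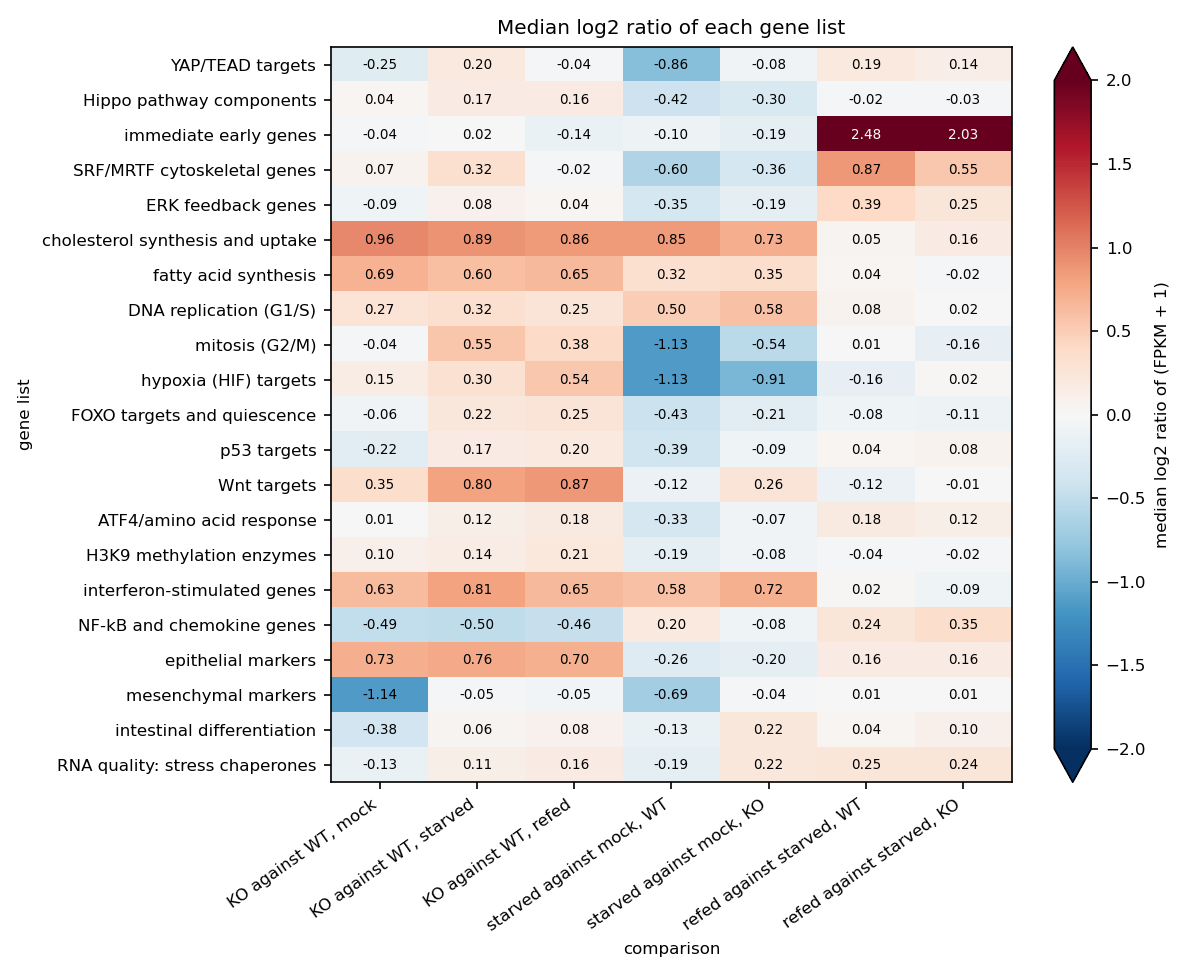
Median log2 ratio of (FPKM + 1), on the deposited scale, of the 21 lists with at least 4 measured genes in the 7 comparisons of single values, with red for higher and blue for lower. The immediate early genes stand out after serum addition, with medians of 2.48 in WT and 2.03 in KO.

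Starved cells were compared with mock cells to describe the response to serum withdrawal. HMGCS1, an early enzyme of sterol synthesis, rose: it was at 5.93 FPKM in mock and 19.0 in starved WT cells and at 14.0 and 47.1 in KO (averaged log2 1.61, SE 0.08, adjusted p = 0.0170). Interferon-induced IFIT3 (log2 1.48) and PARP9 (1.26), the uracil-DNA glycosylase UNG (1.23), the transporter ABCC2 (1.18) and CDRT4 (1.25) rose as well. The hypoxia-induced ANKRD37 fell the most (log2 -2.93, SE 0.21, adjusted p = 0.0170), from 36.3 to 3.12 FPKM in KO, followed by the growth factor PDGFA (-2.89), ANGPTL4 (-2.53), TNFRSF6B (-1.94), LINC00659 (-1.90) and NDRG1 (-1.88).

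In WT alone, IFIT3, HMGCS1, the noncoding ELFN1-AS1, PARP10 and the transporter ABCC3 were among the largest increases, with log2 ratios of 1.68, 1.53, 1.34, 1.34 and 1.33. The largest decreases in WT included THBS1 (log2 -6.61), MMP1 (-6.41), FN1 (-6.17), VWF (-6.14) and VIM (-6.12). They are among the 87 genes 4-fold higher in WT mock than in every other group. THBS1 was at 35.7 FPKM in WT refed and 14.0 in KO refed. The 14 endothelial genes at least 2-fold above every other group in WT mock are lower in WT starved by that definition. In KO the plasminogen activator PLAT went from 8.39 to 33.1 FPKM, and AXIN2, BST2 and ATF5 were higher by log2 1.52, 1.33 and 1.31. PDGFA went from 70.4 to 7.18 FPKM in KO, NDRG1 from 488 to 119, and LOXL2 had log2 -1.74.

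At 2-fold or more, 139 genes were higher and 526 lower in WT, and 128 and 159 in KO, with medians for all genes of -0.19 and -0.06. After median-ratio rescaling the split was 212 and 391 in WT and 141 and 130 in KO, which turns the direction of the KO majority; without the genes 4-fold higher in WT mock the WT split was 139 and 431. Without short RNA features 46 were higher and 477 lower in WT and 33 and 108 in KO. Both genotypes shared 10 of the higher and 63 of the lower genes apart from short RNA; with short RNA these were 38 and 72, against 1.32 and 6.22 for independent lists. Averaged over genotypes 785 genes rose and 2605 fell, 47 and 124 of them at 2-fold or more, with a median of -0.13 for all genes; after median-ratio rescaling 2027 rose and 2002 fell, and without the filter on low values 0 genes were called. With 1 value left out the fit called 23 genes without WT mock, 0 without WT starved, and 2 each without WT refed, KO starved and KO refed, but 4210 without KO mock.

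Sterol genes rose as a group in starved cells: 17 of 24 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.86 and IDI1, ACAT2 and FDFT1 at log2 1.17, 1.09 and 1.08. Camera gave adjusted p = 1.12e-15, and adjusted p = 0.238 with an estimated correlation. Fatty acid synthesis genes rose in 5 of 10 (6 and 2 that rose and fell adjusted over the list alone; adjusted p = 0.00134, and adjusted p = 0.344 with an estimated correlation), with FASN at log2 0.94. DNA replication genes rose in 15 of 23 and fell in 1 (17 and 1 adjusted over the list alone), with the helicase subunits MCM5, MCM4 and MCM2 at log2 1.13, 0.90 and 0.86 and E2F1 at 1.01. Their adjusted p was 9.96e-13, and adjusted p = 0.344 with an estimated correlation. Mitosis genes went the other way: 18 of 22 fell (21 adjusted over the list alone), BUB1, KIF20A, HMMR and CDC20 by log2 -1.33, -1.25, -1.19 and -1.13. Their median was -0.95 in WT, where it uses the mock value that also holds the endothelial transcripts, and -0.49 in KO, a difference without a test. For the averaged comparison camera gave adjusted p = 2.55e-06, and adjusted p = 0.874 with an estimated correlation. Interferon-stimulated genes rose in 11 of 16 (13 adjusted over the list alone; adjusted p = 9.46e-11, and adjusted p = 0.344 with an estimated correlation), with IFIT1 at log2 0.99 and OAS1 at 0.96.

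Hypoxia targets fell in 17 of 20 (18 adjusted over the list alone), with a median of -0.95; besides ANKRD37 and NDRG1, the oxygen sensor EGLN3 fell (log2 -1.43) and the glycolytic HK2 (-1.36). Camera gave adjusted p = 4.94e-07, and adjusted p = 0.748 with an estimated correlation. SRF/MRTF genes fell in 5 of 13 (8 adjusted over the list alone; adjusted p = 0.0260, and adjusted p = 0.874 with an estimated correlation), with the filamin FLNA at log2 -0.72. TAGLN and TPM1, with larger averages of -1.64 and -1.27, had adjusted p = 0.198 and 0.189. TPM1 is among the 87 genes that were highest in WT mock with the endothelial genes, at 56.3 FPKM there and at most 11.3 elsewhere. Hippo components fell in 11 of 20 (13 adjusted over the list alone; adjusted p = 0.0260, and adjusted p = 0.874 with an estimated correlation), among them WWTR1 and the kinase STK3 (log2 -0.79 and -0.72). Of YAP/TEAD targets 1 rose and 3 fell (0 and 2 adjusted over the list alone). ANKRD1 and CRIM1, among the same 87 genes, and CTGF, high there and in WT refed, averaged log2 -2.55, -1.17 and -2.46 with adjusted p of 0.226, 0.215 and 0.173.

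Over all 13456 features 785 rose and 2605 fell on starvation. In some of the other lists these counts were 1 and 5 of FOXO targets (1 and 10 adjusted over the list alone), 0 and 4 of ERK feedback genes (0 and 4), 1 and 3 of p53 targets (1 and 3), 0 and 3 of ATF4 response genes (0 and 0), 0 and 2 of NF-kB genes (0 and 2), 0 and 2 of epithelial markers (0 and 5) and 0 and 2 of H3K9 enzymes (0 and 2). Counts for Wnt targets, mesenchymal markers, intestinal differentiation genes and stress chaperones are not given here. Among immediate early genes these were 0 and 0, with 0 and 0 adjusted over the list alone.

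Refed cells were compared with starved cells to describe the response to serum. The nuclear receptor NR4A1 rose, from 9.42 to 425 FPKM in WT and from 24.9 to 796 in KO (averaged log2 5.15, SE 0.26, adjusted p = 0.00844), with its relatives NR4A3 (4.98) and NR4A2 (4.45). The AP-1 subunit FOSB went from 2.08 to 106 FPKM in WT and 1.5 to 62.7 in KO, and the stress-responsive ATF3 from 6.21 to 244 and 11 to 223. CYR61 also rose (averaged log2 4.91, adjusted p = 0.0404). PNRC1, a nuclear receptor coregulator, fell from 27.6 to 12.5 FPKM in WT and from 26.1 to 11.3 in KO (log2 -1.11, adjusted p = 0.0455), and the cell cycle inhibitor CDKN1B fell (-0.78, adjusted p = 0.0357). BBC3, ZNF503 and HOXB5 (which overlaps antisense transcripts and is uncertain) were lower in WT, with log2 -1.04, -1.04 and -1.03, and C10orf10 in KO, with -1.25.

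At 2-fold or more, 228 genes were higher and 92 lower in WT and 266 and 60 in KO; without short RNA features these were 153 and 8, and 181 and 2. Both genotypes shared 111 higher genes and 1 lower gene apart from short RNA (128 and 15 with it, against 4.51 and 0.410 for independent lists). Averaged over genotypes 104 genes rose and 7 fell, 81 and 5 of them at 2-fold or more. This count was 0 without the filter on low values, and with 1 value left out it was 17 without WT mock, 0 without WT starved, 7 without WT refed, 18 without KO mock, 10 without KO starved and 21 without KO refed.

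Of 18 immediate early genes 13 rose (17 adjusted over the list alone), with adjusted p = 3.44e-33, and adjusted p = 0.360 with an estimated correlation; 16 were at least 2-fold higher in each genotype. SRF/MRTF genes rose in 1 of 13 (10 adjusted over the list alone; adjusted p = 3.51e-11, and adjusted p = 0.386 with an estimated correlation); the gene that rose over all genes, ACTB (log2 1.09), was chosen after its value was seen, and SRF itself averaged 2.30 with adjusted p = 0.0524. ERK feedback genes rose in 2 of 12 (4 adjusted over the list alone; adjusted p = 0.000312, and adjusted p = 0.413 with an estimated correlation), namely the phosphatases DUSP5 (log2 3.55) and DUSP4 (2.27). YAP/TEAD targets rose in 3 of 19 (5 adjusted over the list alone; adjusted p = 3.37e-06, and adjusted p = 0.413 with an estimated correlation), with the kinase NUAK2 at log2 1.96. CTGF averaged log2 3.17 but unevenly, with adjusted p = 0.483.

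NF-kB genes rose in 1 of 10 (4 adjusted over the list alone; adjusted p = 1.92e-05, and adjusted p = 0.386 with an estimated correlation), the gene over all being CXCL2 (log2 1.28). Of the sterol genes 0 rose over all genes and 6 adjusted over the list alone, with adjusted p = 1.09e-05, and adjusted p = 0.360 with an estimated correlation. Camera also placed chaperones (adjusted p = 0.000115; DNAJB1 rose, log2 1.10), epithelial markers (0.00111), the ATF4 response (0.00476) and DNA replication genes (0.0216) above other genes and FOXO targets (0.0237) below them. In that order their values with an estimated correlation were adjusted p = 0.512, 0.386, 0.607, 0.564 and 0.863. The counts that rose and fell over all genes were 1 and 0, 0 and 0, 0 and 0, 0 and 0, and 0 and 1. Adjusted over the list alone they were 3 and 0, 1 and 0, 0 and 0, 1 and 0, and 0 and 2. The DNA replication median of 0.04 on the deposited scale became -0.0046 after upper-quartile rescaling. Of hypoxia targets 1 rose, ANKRD37 (log2 2.57), and of p53 targets 2 rose, PLK3 (1.82) and GDF15 (1.58).

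The responses of KO and WT were subtracted to ask where loss of KDM3A goes with another response. On starvation, MMP1, THBS1, VWF, VIM, BGN and EFEMP1 had the largest differences with the KO response above the WT response, MMP1 with log2 6.30 and THBS1 with 6.23; these are among the 87 genes 4-fold higher in WT mock than in every other group, beside which the endothelial median difference was 2.45. TNFRSF6B, a decoy receptor, had a KO response below the WT response (log2 -1.34), as had UGDH-AS1 (-1.05) and the phosphodiesterase GPCPD1 (-1.0). In all 363 genes were above and 112 below, 274 and 12 without short RNA, and 268 and 112 without the genes 4-fold higher in WT mock; the median of all genes was 0.12. The KO response of mitosis genes was above the WT response by a median of 0.44 relative to all genes, and that of YAP/TEAD targets by 0.34. Both medians were above 100% of matched random lists. Such lists hold unrelated genes, so a list whose genes move together can pass them all through a shift in 1 value. The percentage is therefore no measure of replicate error. NF-kB and chemokine genes had the KO response below the WT response by a median of -0.30, and immediate early genes by -0.27. All of these differences use the single WT mock value, the one that also holds the endothelial transcripts. Of the 5 YAP/TEAD targets above by 2-fold or more, ANKRD1, CRIM1 and TGFB2 are among those 87 genes, CTGF was high in WT mock and in WT refed, and the remaining one is CYR61; TGFB2 was chosen after its values were seen.

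On serum addition the KO response was below the WT response for CTGF (log2 -3.39) and CYR61 (-1.54). CTGF went from 1.24 to 64.0 FPKM in WT and from 1.20 to 5.09 in KO, and CYR61 from 7.66 to 444 and from 16.6 to 309. The chemokine CXCL8 went from 9.37 to 89.8 FPKM in WT and 1.03 to 5.50 in KO. In the other direction, the tubulin gene TUBB2B went from 0.392 to 20.1 FPKM in KO (difference 3.11), CDKN1C from 16.4 to 61.9 (2.16), MT1X from 38.6 to 121 (1.83) and RNF223 differed by 1.67; TUBB2B and MT1X have close paralogs and are uncertain. In all 161 genes were above and 120 below, and 37 and 24 without short RNA. Relative to all genes, the median difference was -0.46 for immediate early genes, -0.29 for SRF/MRTF genes, -0.20 for interferon-stimulated genes, -0.19 for mitosis genes and -0.10 for YAP/TEAD targets. Hypoxia targets had the KO response above the WT response, with a median difference of 0.18. None of these differences has a test.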

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

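Of the tests here, those on fibroblast genes, chromosome segments, other splits of the values and the serum response were chosen only after the result was seen.

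In 4 genes the 2 genotypes responded in opposite directions by at least 1.5-fold; each group has 1 value, so none of these differences was tested. HMOX1, the heme oxygenase, went from 14.8 to 9.45 FPKM on starvation in WT and from 13.6 to 24.3 in KO, a difference of 1.389 on the log2 scale. KRT7, a keratin, went from 25.2 to 4.91 FPKM on starvation in WT and from 7.89 to 15.2 in KO, a difference of 3.02. RGCC, a cell cycle regulator, went from 5.10 to 1.92 FPKM on starvation in WT and from 2.83 to 6.59 in KO, a difference of 2.05. The WT decreases of KRT7 and RGCC rest on the WT mock value, the one that also holds the endothelial genes described next, while for HMOX1 that value is close to the KO mock value. RHOV, a small GTPase, went from 8.94 to 5.18 FPKM on serum addition in WT and from 5.39 to 25.9 in KO, a difference of 2.76.

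The first pattern is the group of matrix and mesenchymal genes that were at least 4-fold higher in WT mock than in every other group, such as VIM at 153 FPKM against 1.29 or less and THBS1 at 175 against 35.7 in WT refed, 14.0 in KO refed and 1.30 or less in the other 3 groups. Fibroblast RNA as the source is argued against by 0 of the 8 fibroblast genes being raised there, with COL1A1 at 23.6 FPKM in WT mock and 50.7 in KO refed. Endothelial RNA in the WT mock value may be the source: 14 of 16 endothelial genes were at 1 FPKM or more in WT mock and at least 2-fold above every other group, and of the 87 genes of the pattern 10 are in the endothelial list, 4 in the mesenchymal and 3 in the YAP/TEAD list. The labels describe a cell line and no sort, and EGFL7 at 44.2 to 84.3 FPKM in the 6 groups shows that HCT116 cells express 1 gene of the list at a high level; among the other 14 the highest value outside WT mock was 5.19 FPKM. A loss of these genes on starvation in WT and with the knockout stays open as the biological explanation: 2 of the 87 genes were 2-fold higher in WT refed than in WT starved, and the time after serum addition is not given.

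The second pattern is the 244 genes, 163 higher and 81 lower apart from short RNA, that differed at least 2-fold between KO and WT in all 3 states. Gains or losses of large chromosome segments between the lines are argued against. For 0% of the 238 genes with neighbours was the median of 20 neighbouring genes shifted by 0.3 or more in the same direction. The median neighbour shift was 0.03, against a median size of 1.56 for the genes themselves. A segment that covers only a minority of the 20 neighbours would not move their median, so smaller gains or losses stay open. The 244 genes themselves were not counted over other splits of the values. For the averaged comparison of KO with WT, splitting the 6 values into 3 and 3 gives 10 splits, too few for a share under 0.05. The real one called 4483 genes, the highest other split 159, and 1 split, the real one, gave as many. In the other splits part of any difference between KO and WT enters the residual, which lowers their counts. The contrast is therefore no measure of chance. The loss of KDM3A and other differences between the 2 lines, such as those of selecting a clone, both stay open and were not tested. In starved and refed cells the WT values also stood apart in low values, with 4300 and 4301 genes at 0 against 7113 and 7075 in KO. Median FPKM of the compared genes was 6.26 and 6.32 in these WT groups and 7.33 and 7.70 in KO. Whether this bears on the averaged calls was not tested.

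The third pattern is the smaller serum response of CTGF and CYR61 in KO. Serum-induced genes were those with a log2 ratio of 1 or more averaged over the genotypes, whether or not they passed the test. A smaller response of all of them in KO stays open for both genes. The log2 ratio of CTGF in KO was 0.303 of that in WT, and that of CYR61 was 0.729. For the other 146 serum-induced genes the median of this ratio was 0.901 and the lower quartile 0.710. CTGF was taken up for its small KO response, and some genes lie below a lower quartile by definition, so its place there cannot decide. By subtraction, 28.1% of the 146 genes (41) had a log2 ratio at least 0.5 smaller in KO, and 28 had one as much larger. The median difference was -0.15. A smaller response of YAP/TEAD targets in KO may be part of the pattern. Of the other serum-induced targets, 60% (3 of 5) had a log2 ratio at least 0.5 smaller, with a median difference of -0.57. Serum-induced immediate early genes had 35.3% (6 of 17) and a median difference of -0.41. With 1 value per group, 5 genes are too few to decide. An effect of the knockout on these genes was not tested.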

How the results depend on the processing

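Alternatives without short RNA features, without genes listed at 0 or without the genes 4-fold higher in WT mock were chosen after seeing the data. The counts and list calls had 151 values under alternatives, of which 88 stayed within 1.5 times the reported one. Named genes had 664 values under other pseudocounts and rescalings. The direction did not change for genes whose reported difference was 2-fold or more. For a ratio of 2 single values this was fixed in advance and shows no robustness. A pseudocount cannot change the sign of such a ratio, and the rescaling factors lay between 0.877 and 1.10, too close to 1 to reverse a 2-fold ratio. Changes of sign in smaller differences were not counted. Of the 252 medians of 21 lists in 12 comparisons, 50 had another sign under at least 1 of the 2 rescalings, the largest of them 0.25 from 0 on the deposited scale. The lists that camera called with the preset correlation had 156 medians under alternatives, of which 1 changed sign: DNA replication genes, refed against starved over both genotypes, at -0.0046 after upper-quartile rescaling.

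In the order KO against WT in mock, starved and refed cells, starved against mock in WT and KO, refed against starved in WT and KO, and the differences of the starvation and serum responses, a pseudocount of 5 gave 288, 216, 280.0, 233, 105, 165, 169, 176 and 143 genes at 2-fold, since it shrinks ratios of low values. A 1.5-fold threshold gave 1577, 1555, 1933, 2293, 1271, 580.0, 578, 892 and 489, since it is lower. A pseudocount of 0.1 gave 906 and 1072 for KO against WT in starved and refed cells, and 1185 and 556 for starvation in WT and KO, since it widens ratios of low values. At 5 FPKM or more, with fewer genes compared, 458 were counted for KO against WT in mock cells, 443 for starvation in WT, 237 and 178 for the differences of the starvation and serum responses, and 184 for the averaged serum response. Without short RNA features the counts were 141 for starvation in KO, 161 and 183 for serum in WT and KO, 286 and 61 for the differences, and 191 for the averaged serum response. Without genes listed at 0 they were 174, 188, 207, 232, 97 and 197 in the same order. The averaged serum count went up under these 3 alternatives, and the cause was not tested.

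The averaged comparisons depended most on the processing. Without a filter, 982 genes were called for KO against WT, 0 for starvation and 0 for serum, and without the variance trend 73 for serum; the cause was not tested. Leaving out 1 value or state gave 5 to 5719 genes for KO against WT, 0 to 4210 for starvation and 0 to 21 for serum, with 1 residual degree of freedom, so that the spread rests on fewer values. With an estimated correlation camera called 0 lists in each averaged comparison, against 7, 8 and 11 with the preset one for KO against WT, starvation and serum. No paired analysis was possible because the columns carry no replicate number and each group has 1 value. A replicate block and leaving out each replicate were not run for the same reason, and a fold threshold was not varied for the averaged comparisons. Without read counts, the precision of low values cannot be given.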

Other observations

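The families of keratin, kallikrein, HOXB and metallothionein genes were chosen after their values were seen, and no test of an explanation is reported here. Keratins, the intermediate filaments of epithelia, were higher in KO: 7, 11 and 10 of 16 measured genes were at least 2-fold higher in mock, starved and refed cells, and KRT7 was at least 2-fold lower in mock cells, with medians of 0.82, 1.0 and 1.06 relative to all genes. KRT15, of basal epithelium, was at 14.1, 7.12 and 7.40 FPKM in WT mock, starved and refed and at 38.7, 26.9 and 32.5 in KO, and KRT13 was at 6.56 in WT mock and 16.1 in KO mock. Of 8 kallikreins, secreted serine proteases, 4, 3 and 3 were at least 2-fold higher in KO and 0 lower, with KLK5 at 0.630 FPKM in WT mock and 14.4 in KO mock, and KLK11 at 0.134 and 3.6. Of 9 HOXB genes, transcription factors of axial patterning, 5 were at least 2-fold lower in KO in each state, with medians of -1.56, -1.89 and -1.72 relative to all genes. HOXB4 was at 6.48, 7.49 and 7.32 FPKM in WT and 0.296, 0.236 and 0.303 in KO, and HOXB8 at 9.99, 21.5 and 17.0 against 0.912, 1.03 and 0.941, while HOXB13 was at 4.79 in WT mock and 5.51 in KO mock. These medians kept their sign under both rescalings. Keratins and kallikreins have close paralogs, and HOXB genes overlap antisense transcripts, so values of single members are uncertain.

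Metallothioneins, which bind metals, were higher after serum addition in KO, with 3 of 5 at 2-fold or more and a median of 1.12 relative to all genes, against -0.17 in WT. MT1X was at 38.6 FPKM in KO starved and 121 in KO refed, MT1E at 341 and 841, and MT2A at 896 and 1956; in WT these were at 77.9 and 67.6, 427 and 440, and 1361 and 1514. Both signs held under both rescalings, and the genes are close paralogs. The 78 ribosomal protein genes had medians between KO and WT of 0.01, 0.21 and 0.29 relative to all genes in mock, starved and refed cells; on the deposited scale these were 0.07, 0.40 and 0.51, and the first became -0.01 after median-ratio rescaling. Of 12 histone genes of the replication-dependent clusters, 1 was at least 2-fold higher in KO in mock cells, 1 in starved cells and 0 in refed cells, and 0 were lower; the medians on the deposited scale were -0.03, 0.18 and 0.24, and that of starved cells became -0.01 after upper-quartile rescaling.

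WT refed values below 0.1 FPKM lay in steps relative to WT starved, with a most frequent ratio of 1.11 shared by 348 of 5047 genes; the next most frequent ratio had 17.0% as many. For the other 4 groups the next ratio had 45.7% to 82.6% as many, so no ratio could be read.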
